A study of Mus musculus with 2 samples.

How the data were processed

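Total RNA of wounded mouse back skin was measured on an Illumina bead array with biotin-labelled target, per the labels' protocols. There were 2 samples, 1 control and 1 knockout, and each was RNA pooled from 3 mice per the series description, which also gives n = 3. The tables used here hold 1 array per group, so the 3 was read as the mice in a pool and the design has no replicate arrays. Groups were taken from the genotype in the labels.

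The authors deposited 2 tables of probe intensity with 25697 probes each. The first holds the mean bead intensity of each probe without normalization, per the file headers, on a linear scale. The second holds the authors' normalized intensity; its columns have nearly equal quantiles (medians 170 and 169.9), its background was not subtracted, and its method is not given in the sources used here. The authors' value table equals the second table at all 25697 probes. GenomeStudio 2011.1 was used, per the submitters' processing notes.

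Both deposited tables also hold a detection p-value per probe, the share of negative control beads at least as bright, in steps of 1 over 798. These p-values do not stand in the row order of the intensities: Spearman's rho across probes between intensity and p-value was 0.00244 in the control and -0.000406 in the knockout, where a strong negative value is built into the measure. The p-values of the 2 arrays correlated with each other (rho 0.927 across probes), as did the intensities (0.941). Of 3504 probes with an intensity above 1000 on both arrays, 1760 (50.2%) were listed with a detection p-value of 0.01 or more on both. Detection depends on intensity alone within an array, so the sorted p-values were given to the sorted intensities of the same array. The use of the p-values as listed was added as an alternative after the data were seen.

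Intensities were normalized with neqc of limma 3.58.1 in R 4.3.3, which subtracts a background fitted by normexp from the negative controls (here inferred from the detection values), adds an offset of 16, applies quantile normalization and takes log2. The offset shrinks folds of dim probes, and quantile normalization gives both arrays one distribution, so a shift of all genes in one direction cannot be seen. A probe counted as detected where fewer than 1% of negative controls were as bright, which held for 12481 control probes (lowest intensity 181.8) and 12412 knockout probes (lowest 177.9). Median intensity before normalization was 177.3 in the control and 173.5 in the knockout, close to these limits. Gene symbols were updated through a RefSeq gene table of mouse assembly GRCm38.p6, used for names only: 25376 probes matched, 23876 of them by accession, 321 kept the symbol of the file, and 21 file symbols read as dates. A gene's value was that of its brightest probe, which gave 17873 genes, 9705 of them detected on at least 1 array.

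With 1 array per group no test was run and no p-value or standard error is given. Genes were counted by a rule of size, at least 2-fold between the arrays and detected on at least 1 of them. For a gene detected on only 1 array, a lower bound of the fold was computed against the higher of its own value and the lowest detected value on the other array. Before the data were examined, 28 lists with 552 genes were fixed for pathways and cell types of wounded skin. For each list the median log2 fold of detected members was set against 10000 random lists of the same size, matched on mean signal in 20 bins. A list was called higher at percentile 97.5 or above and lower at 2.5 or below, with at least 3 detected members. Genes of a list vary together in tissue while random genes do not, so the percentile describes these 2 arrays and says nothing about other mice.

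The genes named were chosen by a rule written before the data were examined. It takes Ctnnb1, the 12 highest and 12 lowest log2 folds among genes detected on both arrays, and the 5 largest lower bounds in each direction among genes detected on 1 array. It also takes up to 4 detected members with the largest absolute log2 fold from each list, and every detected member of the Wnt, hair follicle stem cell and vitamin D lists. Any other gene named was chosen after its value was seen, and this is stated there.

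The procedure was tested on simulated data for the knockout against control comparison, with 25697 probes, shuffled p-values, 200 changed probes and an assumed noise SD of 0.15 (log2) per array. All simulated 4-fold changes (100%) passed 2-fold, and 93% of simulated 2-fold changes passed 1.5-fold in the right direction. The changed probes were drawn only from probes clearly brighter than the detection limits, so these shares leave out the dimmest detected probes. Among unchanged detected probes of any brightness, 1.85% passed 2-fold, under a background spread that was also assumed. The median fitted size was 1.88 for a 4-fold and 0.92 for a 2-fold change on the log2 scale.

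Alternatives were the authors' normalized intensities with a floor of 16, no background correction, median scaling in place of quantile normalization, and an offset of 50. Further ones were detection on both arrays, no detection filter, the mean of detected probes, fold thresholds of 1.5 and 3, and each list without its largest member. Normexp without control estimates, the p-values as listed, and the gene counts without muscle, red blood cell and sex-linked genes were added after the data were seen. The first of these also used the offset of 50, so it changed 2 choices at once. Probe positions within transcripts were not used here. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for counts, lists and plots.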

Results

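The data are gene expression profiles of skin wounds from C57BL6 mice kept on a low calcium diet. In the knockout mice, beta-catenin (Ctnnb1), the adhesion protein and transcriptional partner of the Wnt pathway, was deleted by Cre recombinase in keratinocytes expressing keratin 14. Littermates with floxed alleles and no Cre were the controls. At 3 months of age each mouse received 2 full-thickness back wounds made with a 6-mm punch, and 3 days later the wounds were cut out with an 8-mm punch. Each sample therefore holds wound bed, wound edge and adjoining skin. There was 1 array of RNA pooled from 3 mice for the control and 1 for the knockout. The series concerns the vitamin D receptor in epidermal stem cells and wound repair, and these arrays address what loss of epidermal beta-catenin does to the wound. There are no replicate arrays, so every difference below is between 2 arrays and has no error estimate. Raw intensities ran from 118.5 to 40798.1 in the control and from 120.4 to 40969.4 in the knockout.

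The targeted gene was measured by 2 probes. The brighter Ctnnb1 probe read 2325 in the control and 2344 in the knockout (normalized intensity, log2 fold 0.01), and the other read 1048 and 932 (log2 fold -0.17). The place of these probes relative to the deleted exons is not known here, and the RNA came from whole skin in which cells without keratin 14 kept the gene. These values therefore check nothing about the genotype labels.

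Among genes detected on both arrays, the 4 with the highest folds in the knockout array were Myl2, Myl3, Tnnc1 and Tnnt1, which encode contractile proteins of slow muscle fibres, a grouping made after their values were seen. Myl2, the regulatory light chain of slow and cardiac muscle, was 42.2-fold higher in the knockout array (104 against 4389.9), and Myl3, the matching essential light chain, was 38.5-fold higher (log2 fold 5.27). In the authors' normalized intensities, which keep the background, the folds were 19.6 and 11.7. Red blood cell markers (3 of 4 detected), both detected Y-linked genes, interferon-response genes and Langerhans and dendritic cell markers stood lower in the knockout array. Ddx3y, a Y-linked helicase, was 4.71-fold lower (899 against 191), Alas2, the heme synthesis enzyme of red cell precursors, 4.27-fold lower (2.29-fold in the authors' intensities), and Hba-a1, an alpha-globin, 3.46-fold lower.

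The profiles were otherwise close. Of 9705 detected genes, 58 were at least 2-fold higher and 58 at least 2-fold lower in the knockout array, 1.20% of those detected. In simulated data with an assumed noise SD of 0.15 (log2) per array, 1.85% of unchanged detected probes passed 2-fold, a larger share than that of the genes here. The simulated share covers all detected probes under an assumed background, while each gene here is counted by its brightest probe. The 2 shares are therefore unlike and do not tell how many of the 116 genes are noise. Within 1.5-fold lay 92.0% of detected genes, the quartiles of the log2 fold were -0.19 and 0.18, and Pearson's r across detected genes was 0.987, where genes are not independent replicates. Of the 116 genes past 2-fold, 87 had a mean normalized intensity under 200, where folds are least certain. Only 7 of the 116 had 2 or more detected probes. In 4 of these 7, every other detected probe was at least 1.5-fold in the same direction. Without the muscle, red blood cell and sex-linked genes, a setting chosen after the data were seen, 53 were higher and 53 lower. Median scaling in place of quantile normalization gave 81 higher and 40 lower, and the authors' normalized intensities gave 9 and 12.

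**Figure D1:**
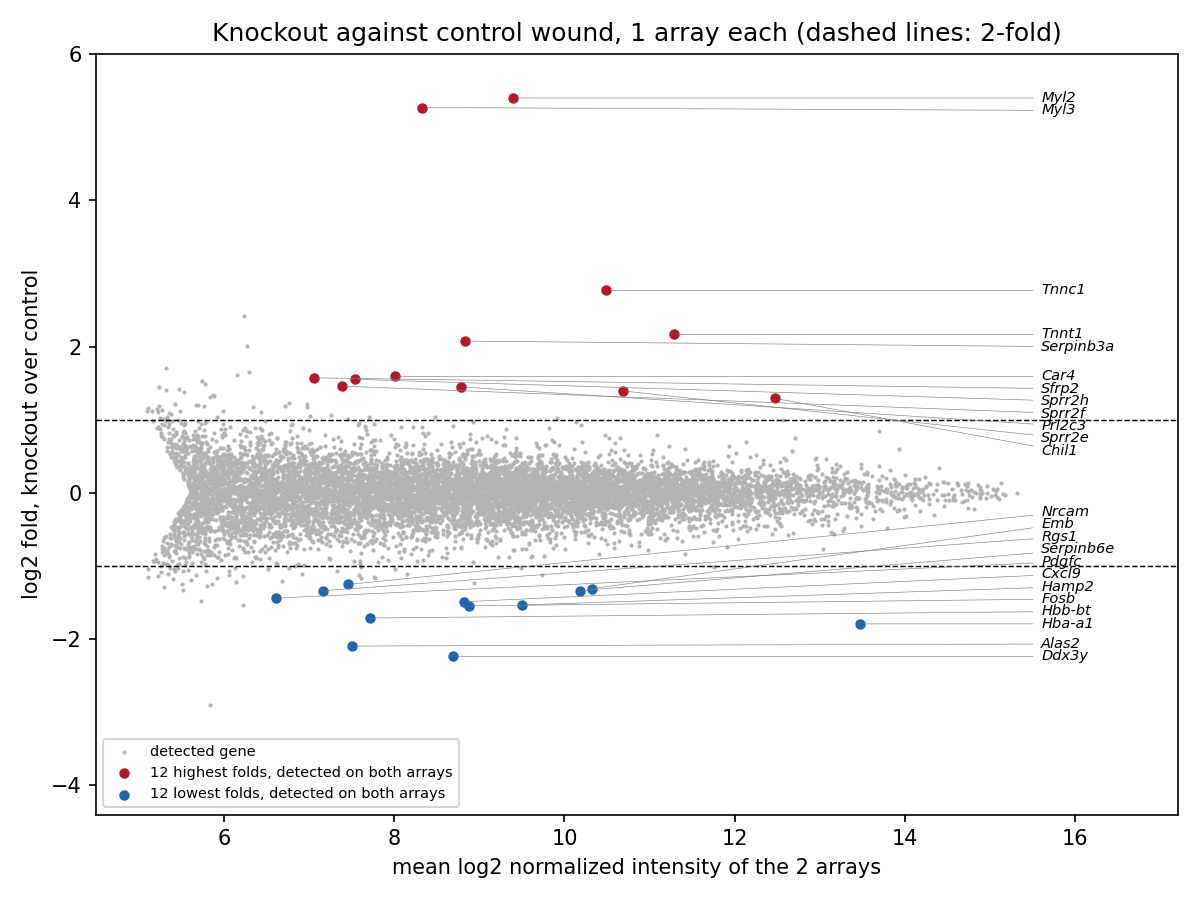
Each point is 1 of the 9705 detected genes, with the mean log2 normalized intensity of the 2 arrays on the horizontal axis and the log2 fold of knockout over control on the vertical axis. Red and blue points are the 12 highest and 12 lowest folds among genes detected on both arrays, from Myl2 (5.40) to Ddx3y (-2.24), and 87 of the 116 genes past the dashed 2-fold lines have a mean normalized intensity under 200.

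Besides Myl2 and Myl3, the slow troponins Tnnc1 (log2 fold 2.77) and Tnnt1 (2.17) led the genes higher in the knockout array. Tnni1, the slow troponin I, was detected in the knockout only, at least 2.87-fold above the control. Next came the serpin Serpinb3a (2.07), the carbonic anhydrase Car4 (1.59) and the secreted Wnt modulator Sfrp2 (1.57), followed by the cornified envelope precursors Sprr2h (1.55), Sprr2f (1.46) and Sprr2e (1.39). The Sprr2 genes are close paralogs that a probe is not certain to tell apart. The rest were the prolactin family member Prl2c3 (1.45, with both probes at 1.32 or more) and the chitinase-like Chil1 (1.29), which was bright on both arrays (3642 and 8909.5). Detected in the knockout only were also Erdr1 (at least 3.59-fold), the keratin Krt42 (at least 3.19-fold), the lipoxygenase Alox8 (at least 2.57-fold) and Bglap (at least 1.93-fold).

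Among genes lower in the knockout array were the beta-globin Hbb-bt (log2 fold -1.71), the immediate-early transcription factor Fosb (-1.55), the hepcidin Hamp2 (-1.53) and the interferon-gamma-induced chemokine Cxcl9 (-1.49). Others were the growth factor Pdgfc (-1.44), the serpin Serpinb6e (-1.34), the G-protein regulator Rgs1 (-1.34), the membrane glycoprotein Emb (-1.31) and the adhesion molecule Nrcam (-1.25). The 3 detected Rgs1 probes differed in size, from -1.42 to -0.27. Detected in the control only were Eif2s3y, the other detected Y-linked gene (at least 3.16-fold), the kallikrein Klk1b24 (at least 2.595-fold), Itga6 (at least 2.19-fold), Pdik1l (at least 2.03-fold) and Hs1bp3 (at least 1.99-fold). In the authors' intensities 9 of the 24 genes with the highest and lowest folds had folds over 1.5 times smaller, among them Sfrp2 (1.69-fold), Pdgfc (1.49-fold) and Rgs1 (1.59-fold), and the 5 higher and 5 lower genes with the largest bounds differed by 1.25-fold to 2.02-fold.

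Genes of the Wnt/beta-catenin pathway were lower in the knockout array as a list. Of 14 detected members, 11 lay below 0 and 4 were at least 1.5-fold lower, and none was 1.5-fold higher. These 4 were the stem cell receptor Lgr5 (log2 fold -1.14, 111 against 50.2, 1.30-fold in the authors' intensities), the Wnt inhibitor Wif1 (-1.03, 1.35-fold in the authors' intensities), Bmp4 (-0.88) and Axin2 (-0.60, 448 against 295), a feedback inhibitor widely used as a readout of the pathway. In the authors' intensities Bmp4 was 1.47-fold and Axin2 1.37-fold lower, so all 4 fell short of 1.5-fold there. Tnfrsf19 stood at -0.55 with its other probe at -0.42. The classical targets Ccnd1 (0.08) and Cd44 (-0.09) hardly differed, although the 5 detected Cd44 probes ran from -0.09 to 0.59, and Myc was detected in the knockout only (0.06). Apcdd1 (-0.16), Nkd2 (-0.14), Twist1 (-0.01) and Sostdc1 (0.29) completed the members detected on both arrays, and Notum and Sp5 were detected in the control only, at bounds of -0.08 and -0.00. The list median of -0.28 lay at percentile 0.67 of the random lists. It was -0.11 with genes detected on 1 array at their bounds and -0.11 in the authors' intensities (percentile 3.33), and without Lgr5 it was -0.16 at percentile 8.1.

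Markers of hair follicle stem cells did not stand apart, with a median of -0.05 at percentile 25.2 over 12 detected members. Apart from Lgr5, the widest differences were Gata6 (-0.57) and Sox9 (0.51). The bulge keratin Krt15 (-0.11, 9107 against 8463), Nfib (-0.17), Tcf7l2 (-0.12), Tcf7l1 (-0.05), Lrig1 (-0.05), Cd34 (0.01), Foxc1 (0.02), Tbx1 (0.06) and Nfatc1 (0.13) were close to 0. The 3 detected Nfatc1 probes ran from -0.29 to 0.18. Of 9 detected hair shaft and inner root sheath genes, 3 were at least 1.5-fold higher (Krt86, Krt84 and Krt33a), each seen in the knockout only. Their bounds were 0.20, 0.80 and 0.17, Krt32 was seen in the control only (bound -0.32), and the list median of 0.12 (0.07 with bounds) lay at percentile 73.2. In the hedgehog list Smo alone was detected (-0.16, with 3 probes from -0.30 to 0.42), and the sebaceous gland list had a median of 0.03 at percentile 63.3, with Elovl3 at 0.75, Awat2 at -0.53, Mc5r at 0.34 and Elovl6 at -0.31.

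Vitamin D and calcium signalling genes, the subject of the series, had a median of 0.07 at percentile 75.8. Atp2a2, a calcium pump of keratinocytes and also of slow and cardiac muscle, was higher in the knockout array on both probes (log2 fold 0.64 and 0.58), on the array where the slow-muscle genes Myl2 (5.40) and Tnnc1 (2.77) were higher too. Cyp24a1, the vitamin D-degrading enzyme, was seen in the knockout only (at least 1.11-fold). The receptor Vdr itself read -0.24 on its brightest probe, with 3 probes from -0.24 to 0.19. Its partner Rxra (-0.15) and the coactivators Ncoa1 (0.39) and Med1 (0.07) showed no common direction. The remaining detected members were Pth1r (0.32), Orai1 (0.18), Pdia3 (-0.14), Cdkn1a (0.11), Atp2c1 (-0.08), Stim1 (0.04) and Pthlh (-0.01).

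Epidermal genes of differentiation and of the wound edge were slightly higher in the knockout array. Of 28 detected differentiation genes, 21 lay above 0 and 3 were at least 1.5-fold higher. These 3 were the transglutaminase Tgm3 (0.80) and the late cornified envelope genes Lce1f (0.79) and Lce1g (0.59), while the desmosomal cadherin Dsc1 stood at -0.57. In the authors' intensities Lce1f was 1.65-fold higher, but Tgm3 and Lce1g only 1.20-fold. The median of 0.11 (0.18 under median scaling) lay at percentile 99.5. The 25 wound-edge keratinocyte genes had a median of 0.15 at percentile 99.8 (0.10 with no detection filter). Of these, 4 were at least 1.5-fold higher, among them Sprr2h, Sprr2e and the S100 protein S100a7a (0.89, 1.33-fold in the authors' intensities). Another 2 were at least 1.5-fold lower. These were the EGF receptor ligands Areg (1.84-fold, 1057 against 575) and Tgfa, which was seen in the control only, too dim to give a bound, and was chosen after its value was seen. Barrier lipid genes had a median of 0.10 at percentile 92.6, with the ceramide enzyme Degs2 at 0.92, the fatty acid transporter Slc27a4 at 0.66, Sult2b1 at 0.43 and Cyp4f39 at 0.40.

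Basal keratinocyte genes (median 0.05, percentile 73.2) and junction genes (0.06, percentile 76.1) did not stand apart. The basal integrin Itga6 was lower, as given above, and the keratinocyte regulator Trp63 stood at -0.46, while Dst read 0.50 and Itgb1 0.53, the latter with probes from -0.22 to 0.53. Among junction genes Pkp2 was at 0.64, Vcl at 0.37 and Dsc3 at -0.42, and Nectin1 was seen in the control only. Cell cycle genes had a median of 0.11 at percentile 93.8, with Plk1 (0.49), Birc5 (0.44) and Foxm1 (0.34) above 0 and Kif11 at -0.81. Housekeeping genes had a median of 0.02 at percentile 58.9. Of these, Hprt read -0.38 on its brightest of 2 detected probes and 0.18 on the other, Rplp0 0.21 and Ywhaz 0.11. B2m read -0.10, or 0.05 under median scaling.

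The immune lists differed in direction. Neutrophil markers were higher in the knockout array, with 15 of 17 detected members above 0 and a median of 0.27 at percentile 100. The median was 0.13 in the authors' intensities, 0.14 without background correction and 0.16 with no detection filter. Lcn2, an iron-binding granule protein also made by keratinocytes, was higher (4273 against 8557), and the chemokine receptor Cxcr2 (0.95), Mmp9 (0.58) and Retnlg (0.54) were higher too. Monocyte and macrophage markers were lower, with 14 of 19 below 0 and a median of -0.16 at percentile 0.27. The mannose receptor Mrc1 was 1.70-fold lower (10952 against 6440.2), Retnla stood at -0.70 and C1qa at -0.35, while Chil3 was 1.85-fold higher. Langerhans and dendritic cell markers had a median of -0.47 at percentile 0, with 11 of 12 below 0. Among them were the Langerhans cell lectin Cd207 (-0.74, other probe -0.87), the class II transactivator Ciita (-0.76) and Cd209a (-0.65), and Xcr1 was seen in the knockout only (bound 0.36).

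Interferon-response genes were lower in the knockout array as well, 13 of 15 lying below 0 and 5 at least 1.5-fold lower. The antiviral gene Rsad2 was 2.34-fold lower (751 against 321). Ifit2 stood at -0.72 and Usp18 at -0.68, with their other probes nearer 0 (-0.38 and -0.26 at the smallest). Mx2, counted among the 5, was seen in the control only (bound -0.30). In the authors' intensities Rsad2 was 2.01-fold lower, but Ifit2 (1.32-fold), Usp18 (1.46-fold) and Mx2 (1.12-fold) fell short of 1.5-fold. The median of -0.48 (-0.39 with bounds) lay at percentile 0, and was -0.27 both in the authors' intensities and without background correction. Cytokines and chemokines had a median of -0.12 at percentile 2.72, just short of the limit set for a call. Within that list 4 genes were at least 1.5-fold lower, among them Cxcl9, Ccl7 (-0.76) and Cxcl10 (-0.72), and Nos2 was seen in the knockout only (bound 0.55). T cell and NK cell markers (median -0.11, percentile 14.96) included Xcl1 at -1.20 (1.41-fold in the authors' intensities) and Il7r at -0.64, while the CD3 chains Cd3g and Cd3d read -0.45 and 0.41. Mast cell markers had a median of 0.04 at percentile 62.6, with Tpsb2 and Tpsab1 at 0.53, Fcer1a at 0.29 and Cpa3 at -0.27.

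The endothelial, fibroblast and hypoxia lists were higher in the knockout array by small amounts. Endothelial markers lay above 0 in 16 of 17 detected members (median 0.20, percentile 99.8), led by VE-cadherin, Cdh5 (0.67), Flt1 (0.47) and Tie1 (0.38), with Sox17 at -0.38. Fibroblast and extracellular matrix genes had a median of 0.10 at percentile 98.0 (0.19 under median scaling). Of these, Fap (0.70), the protease inhibitor Timp1 (0.60 on both probes, 12659 against 19164) and Pdgfrb (0.45) were higher and the proteoglycan Lum lower (-0.53). Hypoxia and glycolysis genes lay above 0 in 14 of 15 members (median 0.23, percentile 99.9), with Pgk1 at 0.72, Egln3 at 0.58, Aldoa at 0.39 and Pfkfb3 seen in the knockout only (bound 0.91).

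Markers of other cells that a wound sample can hold also differed between the 2 arrays. Red blood cell markers had a median of -1.75 at percentile 0 (-1.12 in the authors' intensities and -0.94 with no detection filter), with Slc4a1 at 0.16 apart from the globins and Alas2, and the alpha-globin probe cannot be taken to tell near-identical copies apart. Of the sex-linked genes Ddx3y and Eif2s3y were lower while Xist, near background, read -0.05. That list's median was -2.24 (-1.66 with bounds, -1.01 in the authors' intensities). The 3 detected melanocyte markers were lower, Dct at -0.93 and Mlana and Pmel seen in the control only (bounds -0.81 and -0.36), with a list median of -1.03 (-0.81 with bounds, -0.34 in the authors' intensities). Adipocyte markers had a median of -0.21 at percentile 0.83 (-0.11 in the authors' intensities), with Lpl at -0.52, Car3 at -0.45, Lipe at -0.36 and Plin1 at -0.33. Skeletal muscle markers, a list of fast-fibre and general muscle genes, lay above 0 in 16 of 23 members, with a median of 0.21 at percentile 100. Tcap (0.70), Myh4 (0.67), Myh8 (0.55) and Mb (0.48) were the highest.

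**Figure D2:**
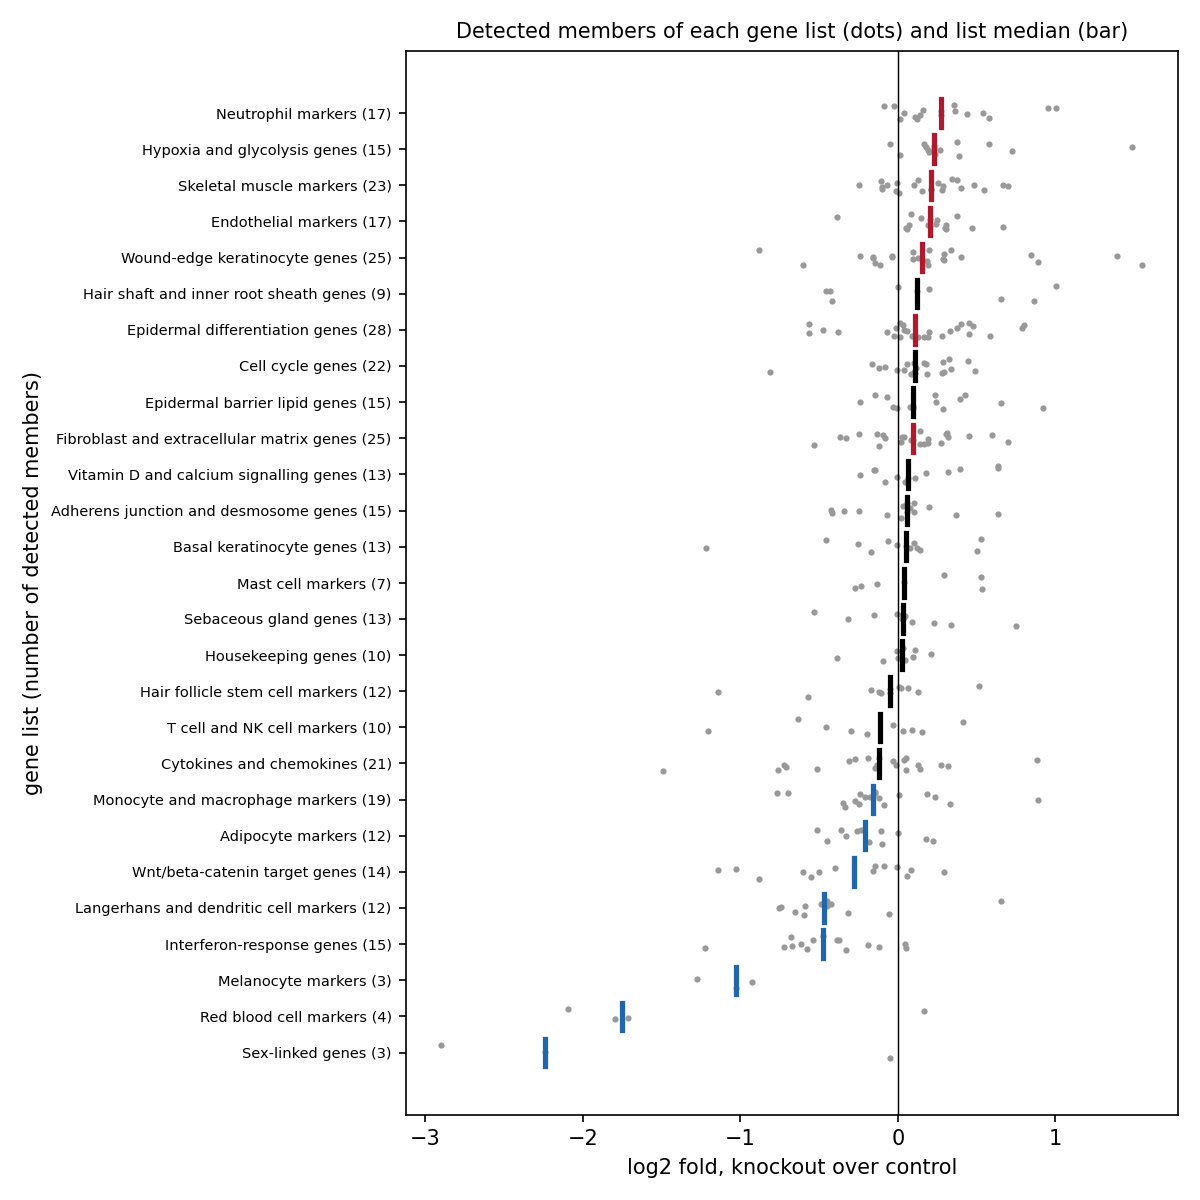
Dots are the log2 folds of knockout over control (horizontal axis) of the detected members of each list, lists are ordered by their median (bar) and the number of detected members stands in parentheses. Red bars mark the 7 lists called higher against random lists, from neutrophil markers (0.27) to fibroblast genes (0.10), and blue bars the 8 called lower, from monocyte and macrophage markers (-0.16) to sex-linked genes (-2.24).

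Of the 27 lists with a percentile, 7 were called higher and 8 lower, where 1.35 lists in all would be for random genes. Genes of a list vary together, so 1.35 is not the number to expect without a genotype effect. The calls for the Wnt, adipocyte, melanocyte, sex-linked and fibroblast lists were lost under at least 1 alternative setting, and the melanocyte median was 0.0252 with undetected genes kept in. With 1 array per group, a difference in cell makeup between pools of mice cannot be separated from a difference due to genotype.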

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

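The settings normexp without control estimates (with an offset of 50), detection p-values as listed, and the counts without muscle, red blood cell and sex-linked genes were chosen after the data were seen. No paired analysis was possible because each group has 1 array, and leaving out arrays was not run for the same reason. All 116 genes past 2-fold kept their direction under each alternative that gave a value for them. Detection settings leave a gene's fold as it is, and the other alternatives rework the same 2 arrays, so this is no independent support. The number of genes past 2-fold depended on how dim probes were treated. Against 58 higher and 58 lower, there were 9 and 12 with the authors' intensities, 9 and 10 without background correction and 16 and 18 with an offset of 50. Normexp without control estimates, which also used the offset of 50, gave 15 and 12. Detection on both arrays gave 25 and 29, and detection p-values as listed gave 33 and 30. At 1.5-fold there were 341 and 434, and at 3-fold 11 and 5. The 21 genes past 2-fold in the authors' intensities were all among the 116, as were 98 of 121 under median scaling. Median scaling moved the median log2 fold of detected genes to 0.03. Background kept in the signal or a larger offset shrinks the folds of dim probes by construction.

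Of the lists called higher, 6 of 7 kept their side of the limit under every alternative that gave a percentile, and 4 of 8 of those called lower. The Wnt list was past the limit no longer with the authors' intensities (-0.11), without background correction (-0.12), with detection on both arrays (-0.16), with no detection filter (-0.14) and without Lgr5 (-0.16). Nor were adipocyte markers with the authors' intensities (-0.11), without background correction (-0.12) or without Lpl (-0.18), fibroblast genes without background correction (0.0839), with no filter (0.0911) or without Fap (0.0911), and sex-linked genes with no filter (-0.25). Melanocyte markers reversed with no filter (0.0252), which adds 6 undetected genes to 3. Cytokines passed the limit with the authors' intensities (-0.10), without background correction (-0.12), with an offset of 50 (-0.12) and with detection on both arrays (-0.125). They also passed it with normexp without control estimates, run at that same offset of 50 (-0.12). With no filter, barrier lipid genes (0.17) and T and NK cell markers (-0.19) passed it. The cause was not tested. Melanocyte and sex-linked lists gave no percentile with detection on both arrays or without their largest member, since fewer than 3 genes remained. Of the other values of named genes under the alternatives, 812 stayed on their side of the fold limit, 141 fell short of it and 1 passed it. The 812 include genes that were short of the limit from the start, so these counts do not give the share of calls that held.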

Other observations

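The tests of the skeletal muscle list, of follicle markers and of the brighter Wnt genes were chosen after the results they bear on were seen. The slow-fibre, immediate-early and X-linked gene sets were written after their patterns were noticed and before their own values were looked at.

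Immediate-early genes, which cells switch on within minutes of a stimulus, were lower in the knockout array. Fos (log2 fold -1.01, 4901 against 2429), chosen after its value was seen, stood beside Fosb (-1.55). Among 16 other detected genes of this class, the phosphatase Dusp1 (-0.57), the stress factor Atf3 (-0.76), the mRNA-decay factor Zfp36 (-0.50), Klf6 (-0.48), Egr2 (-0.38) and Egr1 (-0.37) were lower, while Jun (0.39) and Nr4a2 (0.32) were higher. Their median of -0.35 lay at percentile 0 of matched random lists (-0.30 with genes detected on 1 array at their bounds, -0.21 in the authors' intensities). A lower immediate-early response as a whole may account for this, but these medians stood between the limits set in advance for and against it. These genes also respond to the handling of tissue before RNA is extracted, and the data cannot tell handling from genotype.

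For the higher Myl2, Myl3, Tnnc1 and Tnnt1, a larger share of the same muscle in the knockout sample is argued against as the whole cause. Such a share would raise other muscle genes by about as much. The 23 detected genes of the skeletal muscle list had a median of 0.21 and ranged from -0.25 to 0.70. That median lay at percentile 100 of matched random lists, so a small rise in muscle share is not argued against. The 4 leading genes were picked as the highest folds, so no list member could lie above Tnnt1 (2.17), the lowest of them. That alone is no evidence, and the argument rests on the size of the list's values. A candidate explanation is that the knockout sample held muscle of a slow-fibre type. Of 6 detected slow-fibre genes not looked at before, Myh7 (0.93, bound 0.16), Casq2 (0.85), Myoz2 (0.60), Ankrd2 (0.49) and Csrp3 (0.46) were higher and Tpm3 (-0.15), which non-muscle cells also express, was not. Their median of 0.55 lay at percentile 100. The limits set in advance were a median above 1 for, and a median below 0.5 with no member above 1 against. No member was above 1, and the median of 0.55 lay between the limits. It was 0.48 with Myh7 at its bound and 0.41 in the authors' intensities. Both conditions against were met there, the median by less than the genes' range. Like the skeletal muscle list, these genes rose far less than Tnnt1 (2.17), so the same argument of size weighs on slow-fibre muscle too. That explanation stays open under the main setting only. Whether a genotype effect or a difference in the muscle cut out with the wound lies behind the pattern is untested.

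The lower Wnt targets go in the direction that loss of beta-catenin would give. Fewer hair follicle cells in the knockout sample stay open as a cause: the 11 detected follicle markers off the Wnt list had a median of -0.0519 (median absolute deviation 0.0724), above the -0.28 of the Wnt list, but the gap fell within that deviation once Wnt genes detected on 1 array were set at their bounds (-0.11) and, with a deviation of 0.0684, in the authors' intensities (-0.0513 against -0.1081). Background noise in dim probes could still account for part of it: the 9 Wnt genes with a mean normalized intensity above 200 had a median of -0.14 (-0.10 in the authors' intensities), between the limits set for and against it. An effect of the genotype is a hypothesis that 1 array per group leaves untested.

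The Y-linked Ddx3y and Eif2s3y were lower in the knockout array, and a smaller share of male mice in the knockout pool may be the source. X-linked genes that escape inactivation would then stand higher, yet the 5 detected had a median of -0.20 (percentile 11.8, or -0.07 with bounds), with Ddx3x at -0.57, Kdm6a at -0.20, Eif2s3x at -0.065 Pbdc1 at 0.01 and Kdm5c, seen in the control only, at -0.75 (bound -0.05). Xist, which marks female cells, read -0.05 near background. The sex makeup of the pools therefore stays open, and the labels used here give no sex.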
